A study of Mus musculus with 36 samples.

How the data were processed

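RNA of whole small intestine, LPL preparations, IEL preparations and CD8 IELs of lnc13 WT and KO mice had been sequenced after poly(A) selection, per the labels. Tissue, LPL and IEL libraries were made with a NEBNext Ultra II RNA kit and CD8 libraries with a NEBNext Single Cell/Low Input kit, per the labels' protocols. The 12 deposited gene files of tissue, LPL and IEL hold a raw read count per Entrez gene, made by featureCounts from HISAT2 alignments per the file headers. The submitters' processing notes list TopHat, featureCounts, DESeq and mm10 for them, so the aligner is recorded in 2 ways. The 2 deposited CD8 tables hold a normalised signal per Ensembl gene and library, read counts that the authors had divided by a size factor for each library. This was tested on the values: multiplied by a single factor, each column became whole numbers within 0.01, and these recovered reads served as depth. The submitters' processing notes list STAR, featureCounts, DESeq2, TopHat, DESeq, BWA, deepTools, mm10 and mm39 for the CD8 samples, with no role or version for each. The 6 CD8ab libraries made after gluten challenge and the 6 RNA antisense purification libraries were not used here.

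Symbols were found for 25275 of 27179 Entrez IDs (99.17% of reads) and for 51486 of 78275 Ensembl IDs (98.58% of reads in the unstimulated set and 99.37% in the IL-15 set). Coordinates are from a GRCm38 annotation. Groups and replicate numbers were taken from the sample titles. Tools were R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with pandas 2.3.3. Depth per library is given with the results, and counting error was small beside the spread between libraries for all but the genes near 1 CPM.

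The groups, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined, except where the text says otherwise. The 12 tissue, LPL and IEL libraries were fitted together as 6 groups with edgeR quasi-likelihood, TMM factors, filterByExpr and Benjamini-Hochberg adjustment at 0.05. KO was compared with WT in each preparation, the KO effects were compared between preparations, and preparations were compared over both genotypes. CD8 values were tested with limma-trend on log2(value + 1) for genes with a mean of at least 5, the branch fixed for tables of normalised values. The 2 CD8 tables, normalised apart, were never tested against each other. CPM were computed from the deposited counts with TMM factors.

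Of 52 gene lists for cell types and pathways, those with at least 4 measured members were tested by camera with a correlation preset at 0.01, then with an estimated correlation and by fry, with adjustment over lists. Named genes were, per comparison, up to 10 with the largest rise and 10 with the largest fall among those past the threshold, with a mean of at least 5 CPM and all KO libraries on one side of all WT libraries. Predicted genes and immunoglobulin or T cell receptor segments were left out of naming. The 2 receptor genes of the locus and up to 4 members with the smallest p of each list described were added. Values of some single genes are not reported here.

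Whether replicate numbers pair a WT with a KO library was checked by correlating libraries after removal of group means. Libraries with the same number correlated at 0.615 in tissue, 0.273 in LPL and 0.421 in IEL. With 2 libraries per group the other pairing must give the same value with the opposite sign, so these values cannot show pairing. A replicate block was also fitted as an alternative. In CD8 cells the correlations were -0.039, -0.024 and -0.006 without stimulation and -0.059, -0.124 and -0.113 in the IL-15 set, so there the numbers were taken as shared labels only.

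Alternatives were DESeq2 size factors and its Wald test, other filters and pseudocounts, fits of each preparation alone, and leaving out each library in counts of genes. Those added after the data were seen were the list tests without each library, all alternatives for the comparisons between preparations, leaving out libraries in the correlation between CD8 sets, the fits of 4 libraries alone with a block, the exchange of pair 2 labels, and several CD8 settings. In fits that leave 1 library in a group, that library is assumed to vary like the others.

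The fits were tested on simulated data with 200 genes changed by known folds. Data for blocked fits were drawn from the blocked model itself, so their recovery does not test whether replicate numbers pair libraries. In tissue 13.4% of 2-fold, 80.6% of 4-fold and 87.9% of 8-fold changes were recovered among 14420 genes, with 10 false calls. LPL gave 19.4%, 77.6% and 97% among 14459 genes with 15 false calls, and IEL 9%, 68.7% and 93.9% among 14471 with 3 false calls. The blocked fit of the 4 IEL libraries recovered 94%, 100% and 100% among 12664 genes with 18 false calls. That fit recovered 64.2%, 100% and 100% in tissue with 42 false calls among 13184 genes, and 49.3%, 86.6% and 98.5% in LPL with 86 among 12993. Unstimulated CD8 cells gave 0% at each fold among 9317 genes, and the IL-15 set 17.9%, 71.6% and 87.9% among 13867 with 8 false calls.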

Results

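RNA was sequenced from the small intestine of mice that carried (wild type, WT) or lacked (knockout, KO) the long noncoding RNA lnc13. Of the 36 samples, 24 were analysed here. Whole tissue, lamina propria lymphocyte (LPL) preparations and intraepithelial lymphocyte (IEL) preparations each had 2 WT and 2 KO libraries, from gluten-challenged mice on a DQ8 background. CD8 IELs had 3 WT and 3 KO libraries without stimulation, and 3 of each from the IL-15 set, cells cultured for 48 h with a cytokine that activates intraepithelial lymphocytes. The 6 CD8ab libraries made after gluten challenge and the 6 libraries of lnc13 RNA antisense purification were not analysed here. Reads in genes numbered 10186522 to 13620975 per library for tissue, LPL and IEL, 16428511 to 23762128 for unstimulated CD8 cells and 14724754 to 26997371 for the IL-15 set. Values after ± are SD of the libraries of a group unless named SE.

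The knockout removes a noncoding RNA of the Il18rap neighbourhood, so the 2 receptor genes of that locus were read first. lnc13 itself was not analysed here, and the genotype labels were not checked by its own RNA. Il18rap (gene ID 16174, GRCm38 chromosome 1, 40515362 to 40551707) encodes the accessory chain of the IL-18 receptor. It was near the detection floor in whole tissue, at 0.501 ± 0.342 CPM in WT and 0.942 ± 0.870 in KO (n = 2 each). LPL preparations gave 1.60 ± 2.08 and 0.260 ± 0.245 CPM, and IEL preparations 0.378 ± 0.0308 and 0.660 ± 0.501. In CD8 cells normalised counts were 1379 ± 1252 in WT and 1846 ± 1625 in KO without stimulation, where WT replicate 1 and KO replicate 1 had only 4.35 and 9.16, and 724 ± 562 and 467 ± 162 in the IL-15 set (n = 3 each). Il18r1 (gene ID 16182, chromosome 1, 40465552 to 40500854), which encodes the ligand-binding chain, was 3.62 ± 0.600 and 3.94 ± 0.350 CPM in tissue, 5.59 ± 6.52 and 1.19 ± 0.331 in LPL, and 1.03 ± 0.951 and 1.74 ± 1.45 in IEL. Its normalised counts were 112 ± 172 and 400 ± 605 in unstimulated CD8 cells, and 156 ± 171 and 100 ± 29.1 in the IL-15 set. No difference in either gene passed the test, and each lay within the larger of the 2 SDs.

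The preparations were compared over both genotypes to ask which cells each one held. IEL preparations were rich in T cell transcripts. In them 13 of 14 genes of the CD8 and intraepithelial T cell list and 14 of 17 cytotoxic effector genes were higher than in whole tissue. All 10 smooth muscle genes were lower. Cd3e, a chain of the T cell receptor complex, was 52.8 ± 36.9 CPM in WT IEL and 42.8 ± 17.8 in KO IEL libraries. LPL preparations held less Cd3e than IEL, at 3.87 ± 2.91 and 0.668 ± 0.454 CPM, and their T cell list did not pass against tissue (camera adjusted p = 0.516). Tissue itself had Cd3e at 4.8 ± 2.1 CPM in WT and 8.3 ± 6.0 in KO. In LPL 9 of 13 macrophage genes were lower than in tissue and 0 higher (median -2.88). Plasma cell genes had a median of 2.35 there and did not pass. LPL preparations carried transcripts of the exocrine pancreas, and 12 of 12 such genes were higher than in tissue. Pnlip, the pancreatic lipase, was between 873 and 1526 CPM in the 4 LPL libraries against at most 0.553 in the others. Epcam, which marks epithelium, was 1104 ± 265 and 1261 ± 29.7 CPM in LPL and 1060 ± 141 and 1116 ± 41.7 in IEL. All 10 distal intestine genes were lower in IEL and in LPL than in tissue (medians -2.67 and -4.48), and the ileal bile acid binding protein gene Fabp6 ranged from 3730 to 5739 CPM in tissue libraries. By edgeR, 3230 genes were higher and 3399 lower in IEL than in tissue, 4016 higher and 4118 lower in LPL than in tissue, and 1691 higher and 1165 lower in IEL than in LPL. The last total of 2856 genes became 1290 without KO LPL replicate 1, 1267 without WT IEL replicate 2, 1782 without KO IEL replicate 1 and 1320 without KO IEL replicate 2. Y-linked Ddx3y was 34.0 and 38.7 CPM in replicate 2 of WT and KO tissue and at most 0.109 in the other 10 libraries, which carried Xist of females.

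Whole tissue was compared to ask what the loss of lnc13 did to the gluten-challenged intestine as a whole. Type I interferon response genes were higher in the knockout, 21 of 21 of them, with a median log2 difference of 0.90 (camera adjusted p = 1.04e-05, adjusted p = 0.77 with an estimated correlation). Oasl1, an interferon-induced gene, was 104 ± 38.9 CPM in WT and 289 ± 202 in KO (log2 1.47, SE 0.65). Rsad2, which encodes the antiviral protein viperin, was 7.65 ± 4.47 and 23.7 ± 16.3. NF-kB inflammation genes were higher in 15 of 17 cases (median 0.62, camera adjusted p = 0.000167, adjusted p = 0.77 with an estimated correlation). Among them were the cytokine gene Il18 at 27.6 ± 4.91 and 68.5 ± 28.2 CPM (log2 1.31, SE 0.34) and the NF-kB inhibitor gene Nfkbia at 114 ± 8.40 and 199 ± 89.8. Enterocyte genes were higher (15 of 16, median 0.59, camera adjusted p = 9.85e-05, adjusted p = 0.77 with an estimated correlation), with Krt20, a keratin of mature enterocytes, at 3735 ± 1319 and 6129 ± 1464 CPM. Lipid absorption genes were also higher (11 of 14, median 0.49, camera adjusted p = 0.00072, adjusted p = 0.77 with an estimated correlation). Mttp, which loads lipid onto apolipoprotein B, was 1156 ± 155 and 1998 ± 21.3 CPM, and the triglyceride synthesis gene Dgat2 was 199 ± 28.1 and 343 ± 28.8. All 13 glycolysis genes were higher (median 0.41, camera adjusted p = 1.83e-06, adjusted p = 0.77 with an estimated correlation), with Pfkp at 441 ± 5.34 and 619 ± 73.0 CPM. The lower lists included 15 of 16 cell cycle genes (median -0.56, camera adjusted p = 3.32e-06, adjusted p = 0.77 with an estimated correlation) and 8 of 8 stem cell genes (median -0.56, camera adjusted p = 0.000577, adjusted p = 0.77 with an estimated correlation). Top2a, a topoisomerase of dividing cells, was 101 ± 19.7 and 67.7 ± 7.15 CPM, and the crypt base gene Olfm4 was 120 ± 39.4 and 61.4 ± 29.7.

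In total 16 of 51 lists passed in tissue, 12 higher and 4 lower, and 10 passed without KO replicate 1. None of the 16 held when the correlation was estimated (smallest adjusted p = 0.77 with an estimated correlation). Brush border peptidases and amino acid transport (11 of 13 higher, median 0.43), proximal intestine genes (9 of 10, median 0.92), xenobiotic and retinoid enzymes (13 of 17, median 0.44), the unfolded protein response (12 of 12, median 0.29), mast cells (5 of 6, median 0.92), tight junctions (9 of 12, median 0.08) and immediate early and heat shock genes (9 of 15, median 0.08) were the other lists higher. B cells (11 of 12 lower, median -2.41) and erythrocytes (4 of 4 lower, median -1.55) were the other lists lower. The tissue libraries differed in regional genes. The lactase gene Lct was 81.2 and 211 CPM in replicate 1 of WT and KO and 0.330 and 0.359 in replicate 2. Replicate 2 of both genotypes was also male by Ddx3y. Whether region or sex accounts for the absorptive lists was not tested. Leaving out 1 tissue library makes sex and region unequal between genotypes. A call lost in that way cannot tell dependence on the library from those traits. Mast cells lost their call with a replicate block (adjusted p = 0.122) and without any 1 of the 4 libraries. The interferon call was lost without WT replicate 1 (median 0.52, adjusted p = 0.0524) or KO replicate 2 (0.23, adjusted p = 0.217). NF-kB was lost without KO replicate 2 (0.02), glycolysis without WT replicate 2 (0.22), cell cycle without WT replicate 1 (-0.22) and stem cells without KO replicate 2 (-0.56, adjusted p = 0.076). Enterocytes, lipid absorption, brush border and xenobiotic lists were lost without WT replicate 1 (0.29, 0.20, 0.03 and 0.15) or KO replicate 1 (0.32, 0.07, 0.37 and -0.29). The B cell list was lost without WT replicate 1 (0.51) or KO replicate 1 (-2.28, adjusted p = 0.118). The proximal list was lost without WT replicate 2 (0.39) or KO replicate 1 (0.18), and the unfolded protein response without WT replicate 1 (0.24) or KO replicate 2 (0.12). Immediate early genes were lost without WT replicate 1 (0.14) or KO replicate 2 (0.06), and tight junctions without WT replicate 1 (0.02), KO replicate 1 (0.33) or KO replicate 2 (0.08). Erythrocytes were lost without WT replicate 1 (-1.36), WT replicate 2 (-1.69) or KO replicate 1 (-0.81).

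No single gene passed in tissue by edgeR (0 of 14716, 463 at an unadjusted p under 0.05), and 0 genes passed adjusted over the list alone. Chance would put a share of 0.05 of the genes under that level, and 463 is less, so that count shows no excess. The replicate block in the joint fit gave 0 as well, with 1727 at an unadjusted p under 0.05. A DESeq2 Wald test called 6, named after their values were seen. Hsd17b6, a steroid and retinol dehydrogenase gene, was 4.79 ± 1.29 CPM in WT and 16.8 in KO (log2 1.81, SE 0.27 by edgeR, DESeq2 adjusted p = 0.00101). Gprc5a had a log2 difference of 1.17 and Tnks1bp1 of 1.02. Sec24d, a vesicle coat gene, was 102 ± 3.11 and 170 ± 10.8 CPM, and Midn 219 ± 18.8 and 350 ± 11.3. The immunoglobulin segment Igkv4-59 was lower, at 45.8 ± 38.9 and 4.23 ± 0.450 CPM. Without KO replicate 1 edgeR called 3 genes, Reg3a, Ppp1r15a and Chst4, and Reg3a, an antimicrobial lectin gene, was 389 CPM in KO replicate 2 against 50.9 in KO replicate 1.

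LPL preparations, which also held epithelial and pancreatic transcripts, were compared to ask how the knockout altered cells of the lamina propria. Immune lists of most cell types were called lower in the knockout, but 7 lists were lower without WT replicate 1 against 26 with it. Type I interferon response genes were lower in 21 of 21 cases, with a median log2 difference of -1.65 (camera adjusted p = 2.21e-25, adjusted p = 0.162 with an estimated correlation). Bst2, which encodes the antiviral protein tetherin, was 39.1 ± 3.48 CPM in WT and 13.4 ± 7.91 in KO (log2 -1.55, SE 0.44). The ubiquitin-like gene Isg15 was 14.3 ± 12.1 and 2.15 ± 1.12, and Ifit3 was 4.95 ± 4.56 and 0.476 ± 0.0616. Interferon-gamma response genes were lower in 20 of 20 cases (median -1.38, camera adjusted p = 2.80e-11, adjusted p = 0.229 with an estimated correlation), with the guanylate binding protein gene Gbp3 at 10.8 ± 0.563 and 1.66 ± 1.57 CPM. T cell genes were lower in 16 of 16 cases (median -3.10, camera adjusted p = 2.21e-25, adjusted p = 0.162 with an estimated correlation, and median -0.56 without WT replicate 1), and CD8 and intraepithelial T cell genes in 14 of 14 (-2.54, camera adjusted p = 6.63e-21, adjusted p = 0.162 with an estimated correlation). Cytotoxic effectors were lower in 16 of 17 (-2.51, camera adjusted p = 1.50e-19, adjusted p = 0.162 with an estimated correlation) and eosinophil genes in 4 of 4 (-2.99, camera adjusted p = 3.61e-07, adjusted p = 0.162 with an estimated correlation). Zap70, a kinase of T cell receptor signalling, was 7.51 ± 8.79 and 0.754 ± 0.944 CPM, and the granzyme gene Gzmb 21.9 ± 28.1 and 1.44 ± 1.55. Of the 4 eosinophil genes, Il5ra (1.06 ± 0.305 and 0.0866 ± 0.122 CPM) and Ccr3 (1.98 ± 2.61 and 0.0309 ± 0.0437) lay near the detection floor. Pancreas genes were higher in the knockout in 12 of 12 cases (median 0.47, camera adjusted p = 0.000612, adjusted p = 0.389 with an estimated correlation), with Cpb1, a pancreatic carboxypeptidase, at 793 ± 50.9 and 1287 ± 916 CPM. Lists of 5 epithelial kinds were higher by less, namely distal intestine (0.38), Paneth cells and antimicrobials (0.33, 15 of 15), stem cells (0.26), brush border (0.21) and tight junctions (0.09), as was the pan-epithelial list (0.16), and none held with an estimated correlation (smallest adjusted p = 0.162).

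Altogether 33 of 51 lists passed in LPL, 7 higher and 26 lower. None held when the correlation was estimated (smallest adjusted p = 0.162 with an estimated correlation). WT replicate 1 stood apart, with the cytokine gene Il22 at 33.4 CPM against at most 1.42 in the other 3 LPL libraries. Without it 14 lists passed and 7 were lower. Of the lower lists 6 were still called, with medians of -2.21 for type I interferon, -0.22 for interferon-gamma, -0.56 for T cells, -0.53 for CD8 and intraepithelial T cells, -0.43 for cytotoxic effectors and -1.47 for eosinophils. Another 4 lists turned to higher, namely MHC class II presentation (-2.06 to 1.33), plasma cells (-1.04 to 1.02), dendritic cells (-2.47 to 0.72) and fibroblasts (-1.93 to 1.80). Macrophages (-3.28), B cells (-3.44), NK receptors (-2.97), the Il18rap locus (-2.21, 7 of 9 lower) and the earlier lnc13 targets (-0.49, 5 of 5 lower) were among the lists that lost their call without that library, with medians of -0.25, 0.54, -0.14, -0.11 and -0.07. The earlier targets were also lost without KO replicate 2 (-0.35, adjusted p = 0.0508). Without WT replicate 2 the type I interferon median was -0.72 (adjusted p = 0.0492), and the pancreas list lost its call (0.42) as it did without KO replicate 1 (-0.17). The antimicrobial list was lost without the same 2 libraries (0.08 and -0.32), and distal and pan-epithelial lists without WT replicate 1 (0.19 and -0.04) or KO replicate 1 (0.37 and 0.18). Brush border, stem cell and tight junction lists were lost without WT replicate 1 (-0.05, 0.13 and 0.01) or KO replicate 2 (-0.22, 0.11 and 0.08), and the last 2 also without WT replicate 2 (0.39 and 0.20).

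By edgeR 0 of 14716 genes passed in LPL, with 448 at an unadjusted p under 0.05 and 678 with a replicate block in the joint fit. Both counts are below the 0.05 share of genes that chance would give. Adjusted over each list alone, with no correction across the 51 lists, 9 genes were called lower. These were Il1r1 and Il1rl1 of the Il18rap locus, the NK receptor gene Klrd1, the macrophage genes Adgre1, C1qa, C1qc and Csf1r, and the eosinophil receptor genes Il5ra and Ccr3. Of their 4 lists only eosinophils kept a call without WT replicate 1, at -1.47 in place of -2.99, and the single genes were not tested without it. Il1r1, the IL-1 receptor gene, was 4.12 ± 4.36 CPM in WT and 0.235 ± 0.158 in KO (log2 -4.12, SE 1.15), and the complement gene C1qa was 10.9 ± 13.7 and 0.742 ± 0.437. In KO, Klrd1, Il1rl1, Il5ra and Ccr3 were near the detection floor, at 0.0309, 0.0742, 0.0866 and 0.0309 CPM. DESeq2 called 1 gene, named after its value was seen, the immunoglobulin segment Ighv5-9-1 at 35.2 ± 38.5 and 0.643 ± 0.0519 CPM. Without WT replicate 2, edgeR called 4 genes lower, Il1r2, Cd83, Csf2rb and Rn7sk, and Il1r2 was 36.0 CPM in WT replicate 1 against 1.04 in WT replicate 2.

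IEL preparations were compared to ask how the knockout altered the epithelial compartment that cytotoxic T cells enter. Brush border peptidase and amino acid transport genes were higher in 13 of 13 cases (median log2 difference 0.51, camera adjusted p = 7.13e-08, adjusted p = 0.982 with an estimated correlation). So were 16 of 16 enterocyte genes (0.32, camera adjusted p = 0.000507, adjusted p = 0.982 with an estimated correlation) and 13 of 14 lipid absorption genes (0.24, camera adjusted p = 0.00239, adjusted p = 0.982 with an estimated correlation). Dpp4, a peptidase that trims proline-containing peptides, was 397 ± 121 CPM in WT and 663 ± 236 in KO (log2 0.74, SE 0.41). Glycolysis genes were higher in 11 of 13 cases (0.29, camera adjusted p = 3.58e-05, adjusted p = 0.982 with an estimated correlation), with Ldha, lactate dehydrogenase, at 1356 ± 82.0 and 1837 ± 166 CPM. The Paneth cell and antimicrobial list was called higher (0.28, camera adjusted p = 0.000366, adjusted p = 0.982 with an estimated correlation) with 8 members higher and 7 lower. Its antimicrobial members Sprr2a3 (6.15 ± 2.90 and 81.5 ± 67.5 CPM), Retnlb (0.734 ± 0.660 and 6.43 ± 6.94) and Ang4 (193 ± 146 and 593 ± 178) lay at the top. Tuft cell genes were higher (7 of 8, 0.77, camera adjusted p = 0.00897, adjusted p = 0.982 with an estimated correlation). Enteroendocrine genes were lower (12 of 12, -0.27, camera adjusted p = 0.00223, adjusted p = 0.982 with an estimated correlation, and median 0.18 without WT replicate 1), with the neurotensin gene Nts at 2.84 ± 0.903 and 0.777 ± 0.0558 CPM. Plasma cell genes were lower (9 of 11, -0.83, camera adjusted p = 0.0378, adjusted p = 0.982 with an estimated correlation), with Igha at 779 ± 301 and 329 ± 55.2. T cell genes had a median of -0.39, 16 of 16 lower, and did not pass (camera adjusted p = 0.253). An exocrine pancreas list passed (0.67, adjusted p = 0.982 with an estimated correlation) near the detection floor, with Pnlip at 0 CPM in WT and 0.277 ± 0.391 in KO.

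In IEL 9 of 51 lists passed, 7 higher and 2 lower, and 16 to 25 passed without each of the 4 libraries. None of the 9 held when the correlation was estimated (smallest adjusted p = 0.982 with an estimated correlation). Brush border, glycolysis and antimicrobial lists were called without each of the 4 libraries in turn, at medians of 0.28 to 0.87, 0.25 to 0.37 and 0.23 to 0.47. Enterocyte and lipid lists were lost without WT replicate 1 (0.16 and 0.12), and tuft, enteroendocrine and pancreas lists without WT replicate 1 (0.44, 0.18 and 0.14) or KO replicate 2 (0.11, -0.24 and 0.00). The plasma cell list was lost without WT replicate 2 (-0.46), KO replicate 1 (-0.34) or KO replicate 2 (-0.99, adjusted p = 0.11). By edgeR 0 of 14716 genes passed in IEL (120 at an unadjusted p under 0.05), and 0 adjusted over the list alone. The 120 is far below the 0.05 share of genes that chance would give. DESeq2 called 1, the light chain constant gene Iglc1, named after its value was seen.

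**Figure D1:**
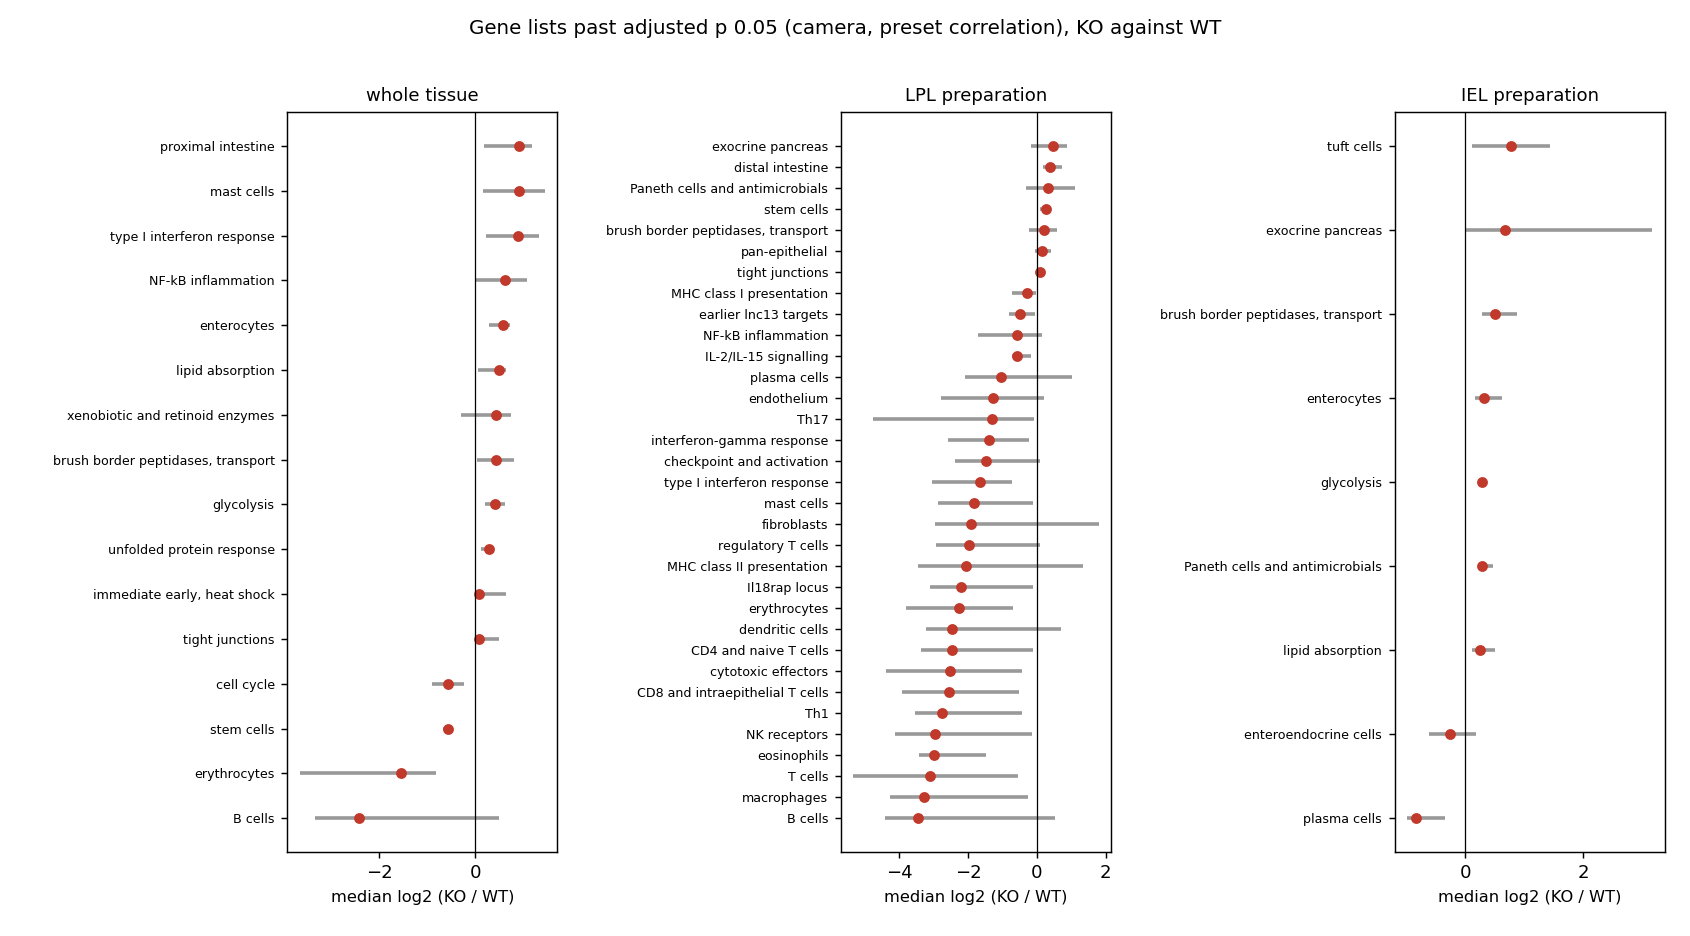
Median log2 KO/WT difference (x axis) of each gene list past an adjusted p of 0.05 by camera with a preset correlation, in tissue, LPL and IEL; grey bars span the medians when each of the 4 libraries was left out in turn. The type I interferon list lay at 0.90 in tissue and -1.65 in LPL.

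Same-numbered libraries correlated positively in tissue, LPL and IEL, which with 2 libraries per group cannot show that they are pairs. The 4 IEL libraries were also fitted alone with a replicate block, which assumes such pairs, a choice made after the data were seen. In that fit 73 of 12844 genes passed by edgeR, 48 higher and 25 lower in KO. The pore-forming gasdermin genes Gsdmc2 (log2 2.29, SE 0.12, edgeR adjusted p = 6.56e-06), Gsdmc3 (2.36) and Gsdmc4 (2.09) rose, and Gsdmc2 was 40.6 and 62.5 CPM in the WT libraries and 207 and 293 in KO. Also higher were Sprr2a2 (4.12), Sprr2a3 (3.59), the defensin gene Defa31 (3.13), the ribonuclease gene Ang4 (1.81) and Duoxa2 (3.05), which matures the oxidase DUOX2. The phospholipase gene Pla2g4c (4.48, SE 0.40) went from 4.42 and 83.5 CPM to 279 and 988, and the glycerol channel gene Aqp7 rose by 2.20. Of the 25 lower genes 17 were immunoglobulin genes or Jchain, against 0 of the 48 higher ones, with Iglc1 at -3.79, Jchain at -1.23, Igha at -1.20 and Igkc at -0.99. The activity-induced transcription factor genes Nr4a1 (-0.74) and Egr2 (-0.81) fell, as did the matricellular genes Ccn1 (-0.82) and Thbs1 (-1.07), the protease inhibitor gene Serpina1b (-2.11) and Rnf39 (-1.16). Gasdermin C, Sprr2a and defensin genes are close paralogs, and how their shared reads were divided is uncertain. The same block gave 0 genes in the joint fit of 12 libraries (569 at an unadjusted p under 0.05), and the 4 libraries alone without a block gave 0. DESeq2 on the blocked 4 libraries called 47, and 45 of the 73 genes were called by both tools in the same direction. With the genotype labels of pair 2 exchanged, the blocked fit called 6 genes in IEL, 74 in tissue and 0 in LPL. The same blocked fit with true labels gave 0 genes by edgeR in tissue (1313 at an unadjusted p under 0.05) and in LPL (200), and 56 and 17 by DESeq2.

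**Figure D2:**
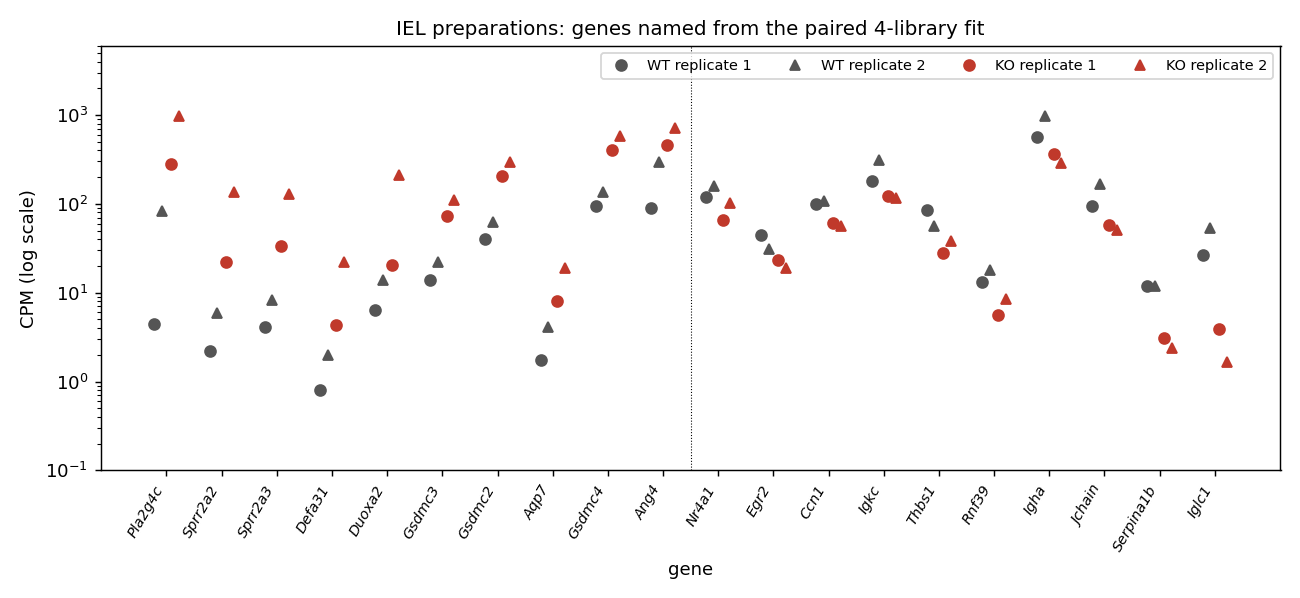
CPM (log axis) of the 20 genes named from the blocked fit of the 4 IEL libraries, with 1 point per library (grey WT, red KO; circles replicate 1, triangles replicate 2). Gsdmc2 lay at 40.6 and 62.5 CPM in WT and 207 and 293 in KO.

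The knockout effects were then set against each other to ask whether they differed between preparations. No gene passed for any of the 3 differences by edgeR (0 of 14716) or DESeq2. At an unadjusted p under 0.05 edgeR had 288 genes for LPL minus tissue and 112 for IEL minus LPL, with a count between these for IEL minus tissue. With a replicate block within each preparation these counts were 1173 and 420, and 634 for IEL minus tissue. With a block by genotype and replicate number they were 204, 58 and 90 in the same order. Of 51 lists camera called 27 for LPL minus tissue, 33 for IEL minus LPL and 12 for IEL minus tissue. None held with an estimated correlation (smallest adjusted p = 0.327, adjusted p = 0.324 and adjusted p = 0.35 with an estimated correlation, in that order). In LPL minus tissue 25 of the 27 were lower. Called in opposite directions in the 2 preparations were 4 lists, type I interferon response, NF-kB inflammation, mast cells and stem cells. The largest of the 4 by its test was type I interferon, with a difference of -2.55 in the median (camera adjusted p = 4.23e-26).

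Unstimulated CD8 IELs were compared to ask whether the knockout changed resting cytotoxic T cells. The cells of both genotypes expressed the CD8 beta chain gene Cd8b1 (24280 ± 6681 normalised counts in WT, 28980 ± 4220 in KO, n = 3), and the granzyme gene Gzma (27560 in WT and 27470 in KO). Gzmk, another granzyme gene and the cytotoxic effector with the smallest p, was 9195 ± 2607 and 13870 ± 1958 (log2 0.63, SE 0.28). Rtp4, an interferon-induced gene, was 1020 in WT and 0.310 ± 0.537 in KO (log2 -9.67, SE 1.21). It was the only gene called adjusted over the list alone, with no correction across the 43 lists. Over all genes limma called 0 of 17208 (575 at an unadjusted p under 0.05) and edgeR on the reads 0 of 9463 (492). The 575 is below the 0.05 share of genes that chance would give, and the 492 is near it. None of 43 lists passed. Expression was patchy between libraries, as 4432 of 10510 genes (42.2%) exceeded 500 in 1 library while another had under 5. Il18rap itself was 4.35 in WT replicate 1 and 2454 in WT replicate 2. Simulated 8-fold changes on this background were recovered in 0% of 65 genes.

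CD8 IELs of the IL-15 set were compared to ask whether the knockout changed T cells driven by a cytokine of inflamed epithelium. T cell genes were lower in KO (13 of 15, median log2 difference -0.34, camera adjusted p = 0.000624, adjusted p = 0.888 with an estimated correlation). The kinase gene Lck was 42030 ± 2536 normalised counts in WT and 33700 ± 1225 in KO (n = 3 each), Cd3d was 20340 ± 612 and 16510 ± 615, and the receptor constant gene Trac was 12470 ± 4932 and 7260 ± 401. Enterocyte genes, at low levels, were lower as well (8 of 11, median -1.21, camera adjusted p = 0.0312, adjusted p = 0.888 with an estimated correlation), with the fatty acid binding gene Fabp1 at 211 ± 59.7 and 65.5 ± 42.3. The T cell call was lost without WT replicate 3 (-0.25, adjusted p = 0.0515), and the enterocyte call without WT replicate 1 (-0.54) or KO replicate 3 (-0.90). The 2 lists became 1 without WT replicate 1, 5 without WT replicate 3 and 6 without KO replicate 2. Adjusted over each list alone, with no correction across the 37 lists, 5 genes passed. Il2rb, the receptor chain shared by IL-2 and IL-15, was 4217 ± 1036 in WT and 7947 ± 1126 in KO (log2 0.93, SE 0.20). Il2rg of the same list was lower, at 54780 ± 3397 and 40600 ± 4850 (log2 -0.44, SE 0.12), and did not pass. Klrc1, which encodes the inhibitory receptor NKG2A, was 454 ± 29.7 and 232 ± 24.7 (-0.97, SE 0.18). The others were Nfkbiz (655 ± 7.75 and 983 ± 94.3) and the fatty acid oxidation genes Acadm (2670 ± 207 and 1834 ± 310) and Ehhadh (16.4 ± 5.95 and 54.0 ± 16.0). Cytotoxic effectors had a median of -0.25 and did not pass (camera adjusted p = 0.0551), with Gzma at 243400 ± 151300 and 224700 ± 80630. Cell cycle genes lay higher in 16 of 16 cases by a median of 0.55, which did not pass either (camera adjusted p = 0.126). Over all genes 0 of 16371 passed by limma (1841 at an unadjusted p under 0.05) and 0 of 14136 by edgeR on the reads (1490).

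With no filter on low values limma called 3 genes, named after their values were seen, mt-Cytb (104300 ± 9420 in WT and 60130 ± 4210 in KO), Gm47585 and ENSMUSG00000135968.1. Without WT replicate 3 it called 1, Gm38111 (log2 6.25). WT replicate 3 had Cd8b1 at 43430 and the gamma-delta receptor gene Trdc at 1897, against 1681 to 6394 and 26590 to 43740 in the other 5 libraries of the IL-15 set. Unstimulated libraries, normalised apart, had Cd8b1 at 19680 to 33310 and Trdc at 2.04 to 991.6. In these genes it was therefore the other 5 IL-15 libraries that lay far from the unstimulated set. Across 12565 genes the KO minus WT log2 differences of the unstimulated and the IL-15 set had a Pearson r of -0.0201 and a Spearman rho of -0.0349, genes not being independent replicates. Unstimulated libraries correlated with each other at only 0.43 to 0.5, so values near 0 cannot tell whether the knockout effects differ between the sets. With 0 genes called in either set there was no overlap to count.

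**Figure D3:**
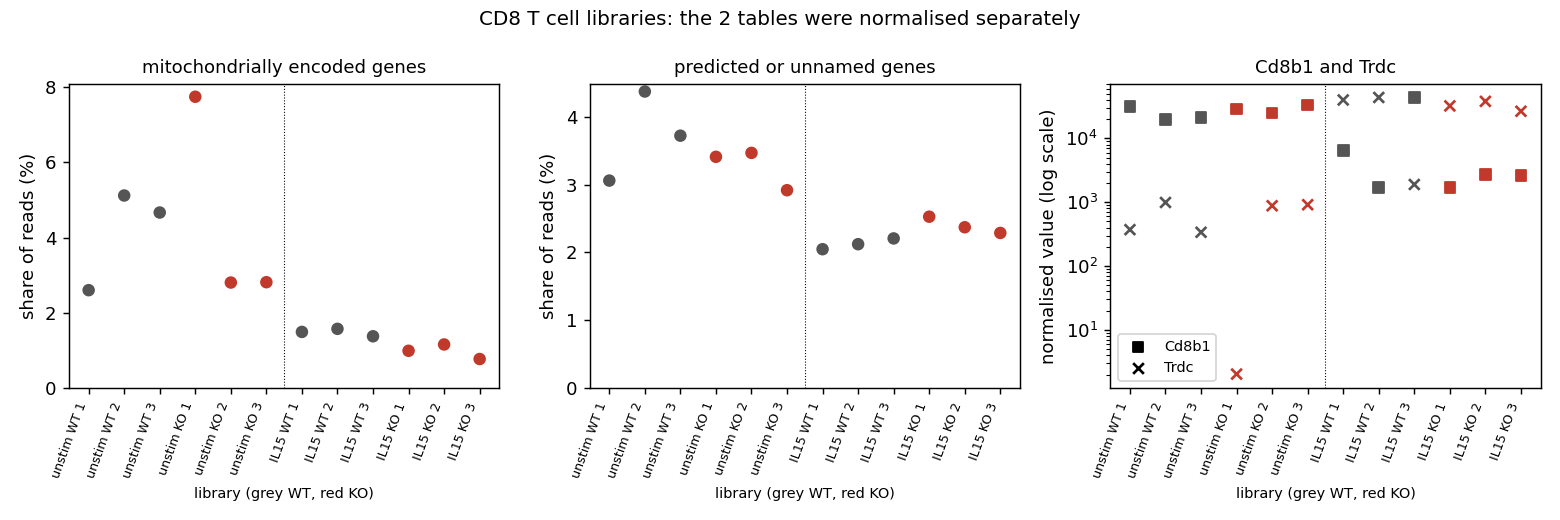
Share of reads (%) in mitochondrially encoded genes and in predicted or unnamed genes, and normalised counts (log axis) of Cd8b1 (squares) and Trdc (crosses), for each of the 12 CD8 libraries (grey WT, red KO; the 2 sets were normalised separately). In the IL-15 set WT replicate 3 had Cd8b1 at 43430 and Trdc at 1897.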

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

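The tests by leaving out libraries of each difference, and the pancreas share, were chosen only after the results were seen. Each of the 4 results here is a gene list whose knockout effect was called in opposite directions in LPL and in whole tissue, with the difference itself tested. For the type I interferon response the knockout effect in LPL minus that in tissue was -2.55 in the median (camera adjusted p = 4.23e-26, adjusted p = 0.327 with an estimated correlation), from 0.90 in tissue and -1.65 in LPL. It was called without each of the 8 libraries in turn, at -1.66 to -3.71. For NF-kB inflammation the difference was -1.57 (camera adjusted p = 7.34e-10), from 0.62 and -0.58. Without WT LPL replicate 1 it was -0.48 and no longer called (adjusted p = 0.0567), and without KO tissue replicate 2 it was -0.39. For mast cells it was -2.77, from 0.92 and -1.82, and -0.90 without WT LPL replicate 1 (adjusted p = 0.0261). For stem cells it was 0.70 (camera adjusted p = 2.86e-05), from -0.56 in tissue and 0.26 in LPL. None of the 4 held with an estimated correlation.

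In LPL 26 lists, most of them of immune cells or responses, were called lower in the knockout by camera. None of them held with an estimated correlation (smallest adjusted p = 0.162). A candidate explanation for the lower lists is the high immune cell content of WT replicate 1. Without that library 7 lists were lower in place of 26, as that explanation needs, while T cell, cytotoxic and both interferon lists were still among the 7. A pancreas share that differs between groups would have to dilute epithelial genes too, and the pan-epithelial list lay at 0.16, against -3.10 for T cells and 0.47 for pancreas, which argues against it. A loss of interferon-responding cells in the knockout LPL preparations stays open. Replicate 2 of WT and KO tissue was male by Ddx3y, of which LPL libraries had at most 0.0618 CPM. Those tissue libraries thus came from other animals than the LPL libraries. All 10 distal intestine genes were also lower in LPL than in tissue over both genotypes (median -4.48). Whether other animals or gut region account for the opposite calls in LPL and tissue stays open.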

How the results depend on the processing

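The fits of 4 libraries alone with a replicate block, the list tests without a library and the CD8 settings named here were chosen only after the results were seen. Where a value differed from the main one, the cause was not tested. DESeq2's Wald test called 6 genes in tissue, 1 in LPL and 1 in IEL, where edgeR called 0. With the 4 libraries alone and a block, DESeq2 called 56, 17 and 47 genes and edgeR 73 in IEL. Lists past the threshold were 0 in tissue, LPL, IEL and the IL-15 set with an estimated correlation and 0 by fry. IEL lists numbered 15 with the 4 libraries alone and 17 with a block as well. With the replicate block in the joint fit, lists numbered 16, 34 and 11 and genes 0. Genes at an unadjusted p under 0.05 then rose from 463 to 1727 in tissue, 448 to 678 in LPL and 120 to 569 in IEL. Of these counts only 1727 exceeded the 0.05 share of genes that chance would give. In the IL-15 set limma called 3 genes with no filter on low values, and the correlation with the unstimulated set was -0.0349 by rank. Leaving out each library in turn gave 0 to 3 genes in tissue, 0 to 4 in LPL, 0 to 0 in IEL and in unstimulated cells, and 0 to 1 in the IL-15 set. Lists then numbered 10 to 18 in tissue, 14 to 36 in LPL, 16 to 25 in IEL, 0 to 1 in unstimulated cells and 1 to 6 in the IL-15 set. Genes that differed between preparations numbered 4685 to 6926 for IEL against tissue, 6602 to 7981 for LPL against tissue and 1267 to 2804 for IEL against LPL, and the correlation between CD8 sets ran from -0.036 to 0.006. A replicate block in the CD8 sets gave 0 genes and 0 and 3 lists. The other settings run left counts of called genes and lists within 1.5 times. Depth limits genes near 1 CPM such as Il18rap in tissue.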

Other observations

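The test of an epithelial share, the test for a common effect in all preparations and the counts of genes over other splits of the samples were chosen only after the results were seen. More single genes were called higher in the knockout in the blocked fit of the 4 IEL libraries. Car4, a carbonic anhydrase of the brush border, was 132 ± 12.9 CPM in WT and 294 ± 30.1 in KO (n = 2). The amino acid transporter gene Slc6a19 had a log2 difference of 0.88 (SE 0.12), and the peptide transporter gene Slc15a1 was 171 ± 74.7 and 307 ± 145. The goblet cell gene Clca1 was 1514 ± 803 and 2843 ± 883 CPM, Reg4 64.6 ± 5.81 and 105 ± 10.7, and Trpm5, the cation channel of tuft cells, 13.2 ± 7.86 and 24.2 ± 11.7. The class II genes Cd74 (257 ± 243 and 140 ± 132) and H2-Eb1 (80.1 ± 67.1 and 51.9 ± 43.9) were among the 25 lower ones. KO and WT libraries overlapped for Slc6a19, Slc15a1, Trpm5, Cd74 and H2-Eb1. Calls of these genes rest on the assumed pairs, and they fall outside the rule for named genes. In the joint fit of 12 libraries with a replicate block, Gsdmc2 had a log2 difference of -0.69 (SE 0.39) in tissue and 0.80 (SE 0.38) in LPL. Gsdmc3 (-1.21 and 0.74) and Gsdmc4 (-0.99 and 1.11) went the same ways, and none of these was called.

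In the IL-15 set predicted or unnamed genes held 2.13 ± 0.080% of reads in WT and 2.40 ± 0.122% in KO, and mitochondrially encoded genes 1.48 ± 0.099% and 0.971 ± 0.194% (n = 3, exact permutation p = 0.1 for both, two-sided and the smallest this design allows). Of 1089 genes higher in KO at an unadjusted p under 0.05, 43% were predicted genes, and of 752 lower ones 8%, against 35.1% and 20.1% of all tested genes that lay higher and lower. Unstimulated cells gave 3.72 ± 0.658% and 3.27 ± 0.303% for predicted genes and 4.13 ± 1.34% and 4.46 ± 2.85% for mitochondrial ones (exact permutation p = 0.4 and 0.8). IL-15 WT replicate 1 alone of its set had Y-linked Ddx3y, at 2765 normalised counts. In the unstimulated set Ddx3y ranged from 0 to 3640, and patchy expression there leaves the sex of single libraries uncertain.

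The 48 genes higher in KO in the blocked IEL fit could have come from a larger epithelial share in the KO libraries. The pan-epithelial list lay at 0.08 (SD 0.11), which argues against an epithelial rise as large as the 1.13 median of the 48 genes. Those genes were picked by this same fit, so their median had to lie above that of an unselected list. The T cell list lay at -0.34 (SD 0.29), and a larger share of mature enterocytes alone was not tested. A more proximal or distal piece of intestine would move the regional lists apart, and the proximal minus distal gap was -0.05 (spread 0.48), which argues against that for the 48 genes as a set. A knockout effect common to the epithelium of all preparations cannot be told apart from none: the 48 genes lay at a median of 0.30 in tissue (34 higher, 0.33 in pair 1 and 0.01 in pair 2) and 0.27 in LPL (40 higher, 0.40 and 0.14). An effect of lnc13 loss on IEL-adjacent epithelium stays open, as does position for single genes, since Gsdmc2 was 438 and 24.2 CPM and Pla2g4c 3804 and 19.5 in WT tissue replicates 1 and 2, which differed in regional genes.

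The higher predicted and lower mitochondrial shares of the IL-15 KO libraries might reflect more unspliced or nuclear RNA, in which genes of long genomic span would be higher. The smallest rank correlation with span over the 9 KO minus WT pairs was -0.031, inside the range of pairs within a group (up to 0.163 in size, taken with either sign), which had been set beforehand as evidence against it. That bound was wrong for a small shift, since the 9 pairs had a median of 0.08 in the direction of the explanation and reached 0.233, so it cannot be told apart from variation between libraries. Without WT replicate 3, with its other T cell receptor transcripts, the smallest gap between KO and WT libraries was still 0.33 percentage points for mitochondrial shares and 0.17 for predicted shares, which argues against that library as the source. An effect of genotype on the cultured cells stays open.

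Other splits of the 6 libraries into groups of 3 give 10 splits, too few for a share under 0.05. Where the real count was 0 no split can give fewer, so the 10 of 10 for genes in unstimulated cells and in the IL-15 set (highest other 0 in both) and for lists in unstimulated cells (highest other 3) tell nothing. Genes at an unadjusted p under 0.05 numbered 1841 in the real IL-15 split and at most 800 in the others. In unstimulated cells they numbered 575, against up to 784 in the others. For lists in the IL-15 set the real count was 2 and the highest other 8, and 9 of 10 splits, the real one included, gave as many.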
